A study of Mus musculus with 16 samples.

How the data were processed

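Messenger RNA was measured by sequencing in mouse livers from 2 groups, 8 libraries labelled as control CRISPR and 8 labelled as Cyp7a1 CRISPR, all from mice fed a Western diet for 8 weeks. Per the labels' protocols, total RNA came from flash-frozen tissue and mRNA libraries were made with a KAPA RNA HyperPrep kit. The labels do not say in so many words that each library is a separate animal, so p-values measure the spread between these samples. They give no batch, litter, sex or pairing, and the groups share no replicate numbers, so no covariate and no pairing entered the tests.

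The deposited table holds a signal per gene and library, normalized counts, for 12618 genes and 16 libraries, and no column was left without a sample. Per the submitters' processing notes, Trim Galore 0.6.10, STAR 2.7.11a, featureCounts, DESeq2 and R 3.6.3 were used with the genome build mm10. The notes give neither the role nor the order of these tools. The annotation release, the strand setting of the counting and the rule that chose the genes in the table are not given in the sources used here. Because the strand setting is unknown, reads from overlapping genes may be assigned to either gene.

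In each library the values were whole multiples of a step, the size of 1 read, which lay between 0.769 and 1.54. Dividing by this step gave whole reads for 99.937% to 99.992% of values, with a tolerance of 0.05 reads. The recovered reads summed to between 13.8 and 27.4 M reads (M, mega) per library. The smallest value above 0 was 1 read in 6 libraries and more than 1 read in 10, so the step of each library was fitted to all of its low values. The count tests on recovered reads, edgeR and DESeq2, use all 16 libraries and are alternatives, never the main result.

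One cell, for Ccne2 in Cyp7a1 2, held text in place of a number, and Ccne2 was left out of the tests. Symbols turned into dates, 19 in all, were replaced by the symbol of their gene ID. Of the gene IDs, 12594 matched the GENCODE M21 symbol table. Coordinates are those of GENCODE M21 on GRCm38 (mm10), 1-based.

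The main test was limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3 on log2(value + 1), two-sided, with Benjamini-Hochberg adjustment over 12617 genes and a threshold of 0.05. Fold changes are Cyp7a1-labelled minus control on the log2(value + 1) scale, which understates the change of low genes. The 95% intervals use limma's moderated standard errors and degrees of freedom. A minimum mean of 10 was set, but the lowest gene mean was 13.3, so it removed no gene. The Cyp7a1 transcript was also tested by a two-sided exact permutation test over 12870 assignments.

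Gene lists, 30 in all, were tested with camera at a preset inter-gene correlation of 0.01 where at least 3 members were in the table, which left 28 lists. The list of sex-linked genes served only as a label check, and the neutrophil list had 1 tested member. The test was repeated with an estimated correlation and with fry, which tests whether a list's own genes move on balance one way. A list not called by these tests can still hold members that changed in both directions. The members counted as higher or lower are given over all genes tested and adjusted over the list alone. A list score is the mean over members of log2(value + 1) after centring each gene over all libraries.

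Named genes follow a rule set with the lists, the main test and most alternatives before the data were examined. It takes Cyp7a1, the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold with a mean of at least 50, and for each list the up to 4 members with the smallest p past the threshold, or 2 where none passed. Predicted genes, identifier-only symbols, pseudogenes and mitochondrial or ribosomal RNA genes were left out of the largest changes. This removed 53 genes past the threshold, 4 of them with changes as large as those named. The pattern that recognises identifier-only symbols was written out after the data were seen.

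Alternatives were a pseudocount of 8, no filter, a minimum mean of 50, quantile normalization, scaling to equal totals, array weights, edgeR 4.0.16, DESeq2 1.42.0, leaving out each library in turn, and a change of at least 1.5-fold. A further pair was chosen after seeing the data, leaving out Control 20 together with Cyp7a1 24 and a macrophage and fibrosis score as a covariate.

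The steps were tested on simulated data with the real means and library sizes, 200 of 12617 genes changed. With 8 libraries against 8, limma recovered 77% of the 100 genes changed 1.5-fold and 95% of the 100 changed 2-fold, with 2.27% of calls false. The values for edgeR were 78%, 95% and 1.7%, and for DESeq2 82%, 97% and 8.21%. When the glucose metabolism list was raised 1.5-fold in the simulation, camera called it and called 0 of 25 lists that share no member with it. The simulated genes were drawn independently of each other, while real lists vary together, with an estimated correlation of 0.646 for cholesterol synthesis and uptake. The simulation therefore does not show how often limma or camera at the preset correlation makes false calls among correlated genes. Single libraries far from their group were sought with Dixon's criterion in Python 3.11.15.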

Results

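Livers of mice fed a Western diet for 8 weeks were profiled by mRNA sequencing in 2 groups, 8 control CRISPR libraries and 8 Cyp7a1 CRISPR libraries. CRISPR is a gene editing method, and Cyp7a1 encodes the rate-limiting enzyme of classical bile acid synthesis. The series concerns bile acids and lipid metabolism, and its design gives 1 comparison, Cyp7a1 against control on the same diet. Recovered reads were 21.02 ± 3.48 M per control library and 23.4 ± 2.41 M per Cyp7a1 library (SD, n = 8 each; M, mega), with a range of 13.8 to 27.4 M reads. The 10 most abundant genes took 18.1% to 21.3% of each library.

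The targeted gene was not lower in the libraries labelled Cyp7a1. Cyp7a1 (ENSMUSG00000028240, chromosome 4, 6265612 to 6275633 on mm10, minus strand) had 3587 ± 1252 normalized counts in controls and 4702 ± 1126 in the Cyp7a1 group (SD, n = 8 each). Control libraries spanned 2148 to 5642 and Cyp7a1 libraries 3069 to 5873, and 6 of the 8 lay above the control mean. The log2 fold change was 0.43 (95% interval 0.01 to 0.84), with a limma adjusted p of 0.227 and a two-sided exact permutation p of 0.0716. Counts per gene do not show whether the coding sequence was edited, so the group is called Cyp7a1-labelled throughout, and every direction below rests on these labels.

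**Figure D1:**
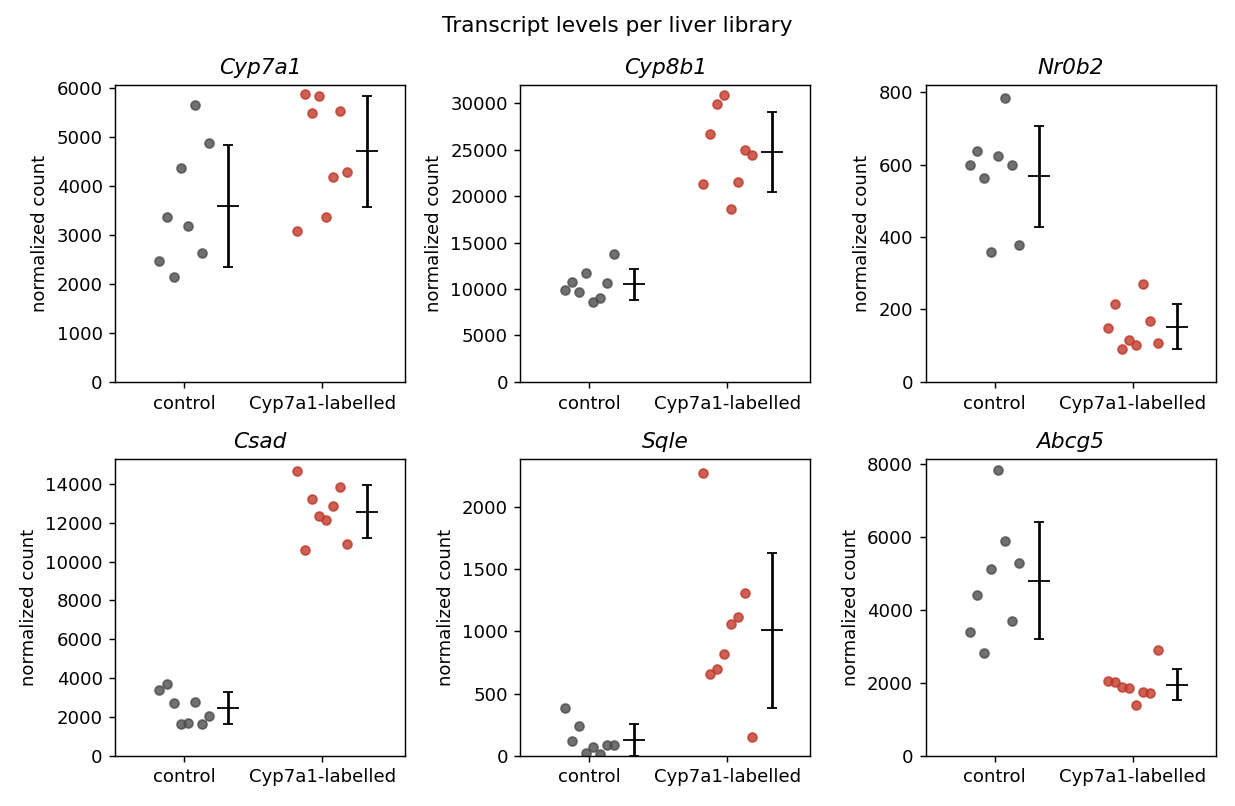
Normalized counts (vertical axes, linear from 0) of 6 genes in each control (grey) and Cyp7a1-labelled (red) library; each point is 1 library, and black marks give the mean ± SD of 8. Cyp7a1 overlaps between groups, while every Cyp7a1-labelled library lies above every control for Cyp8b1 and Csad and below every control for Nr0b2.

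Of 12617 genes, 387 were higher and 385 lower in the Cyp7a1-labelled livers (limma, adjusted p under 0.05). The change was at least 1.5-fold for 111 higher and 83 lower genes and at least 2-fold for 46 and 24, and the median log2 fold change of all genes was 0.0034. The groups did not overlap for 64 higher and 67 lower genes, where chance gives 0.0155% of genes. The counts fell to 230 higher and 245 lower without Cyp7a1 28, and to 261 and 256 without Control 16. With a macrophage and fibrosis score as a covariate, chosen after seeing the data, they were 655 and 654.

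The largest rises included Tff3, a secreted trefoil peptide, from 9.80 ± 7.36 to 136 ± 110 normalized counts (12.4-fold, adjusted p = 0.000189). Its log2 fold change was 3.63 and shrank to 2.83 with a pseudocount of 8, since its control counts were low. Csad, which makes the taurine precursor hypotaurine, rose from 2433 ± 827 to 12575 ± 1378 (5.41-fold, adjusted p = 1.42e-07). Nipal1, a magnesium transporter family member, rose by 2.63 ± 0.31 on the log2 scale (SE), and Asns, asparagine synthetase, by 2.24 ± 0.38. Cyp17a1, a steroid hydroxylase, rose by 2.00 ± 0.34, and Ugt1a9, a glucuronosyltransferase, by 1.62 ± 0.33. The remaining 6 of the 12 largest rises, Sqle, Fdps, Msmo1, Mvd, Cyp51 and Nsdhl, all belong to cholesterol synthesis. Ugt1a genes share exons, so reads of Ugt1a9 and Ugt1a1 may be exchanged between them.

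The 12 largest falls included Nr0b2 (SHP), a nuclear receptor repressor of bile acid synthesis genes, from 568 ± 139 to 152 ± 62.6 normalized counts (log2 fold change -1.95, adjusted p = 4.25e-05), and Cidea, a lipid droplet protein, with a log2 fold change of -2.29 ± 0.50 (SE). That of Cidea was -2.91 without Control 20 and Cyp7a1 24, a pair chosen after seeing the data. Krt23, a keratin, changed by -2.15 ± 0.31 and Hsd17b6, a steroid dehydrogenase, by -1.73 ± 0.22. Spry4, an inhibitor of receptor tyrosine kinase signalling, changed by -1.69 ± 0.28, Sema5b, a semaphorin, by -1.28 ± 0.10 and the transcription factor Bach2 by -1.27 ± 0.22. Cyp2d40 changed by -1.30 ± 0.11, Derl3 by -1.31 ± 0.33 and Lrtm1 by -1.49 ± 0.43. The major urinary protein genes Mup17 and Mup2 changed by -2.24 ± 0.46 and -1.28 ± 0.35. Mup and Cyp2d genes have near-identical copies between which reads may be split, so the values of single members are uncertain.

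The list of cholesterol synthesis and uptake genes was higher by the list test with a preset correlation (camera adjusted p = 6.98e-21). The call was lost with an estimated correlation (adjusted p = 0.235), the list's inter-gene correlation being estimated at 0.646. Of 24 members, 17 were higher and 0 lower over all genes tested, 22 were higher adjusted over the list alone, and all 24 fold changes were above 0 (median 0.86). Squalene epoxidase, Sqle (chromosome 15, 59315077 to 59331192), went from 127 ± 126 to 1009 ± 623 normalized counts, with a log2 fold change of 3.37 ± 0.63 (SE). Fdps rose by 1.87 ± 0.31, Msmo1 by 1.61 ± 0.22, Cyp51 by 1.501 ± 0.272, Nsdhl by 1.45 ± 0.27 and Dhcr7 by 0.98 ± 0.17. Srebf2, the transcription factor that drives these genes, rose by 0.55 ± 0.09. The fry adjusted p was 0.00397, and the list score differed between the groups with an exact permutation p of 0.000777. Cyp7a1 36 had a score of -0.519, within the control range of -1.16 to -0.0454, while the other 7 Cyp7a1-labelled livers had scores of 0.361 to 1.32.

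**Figure D2:**
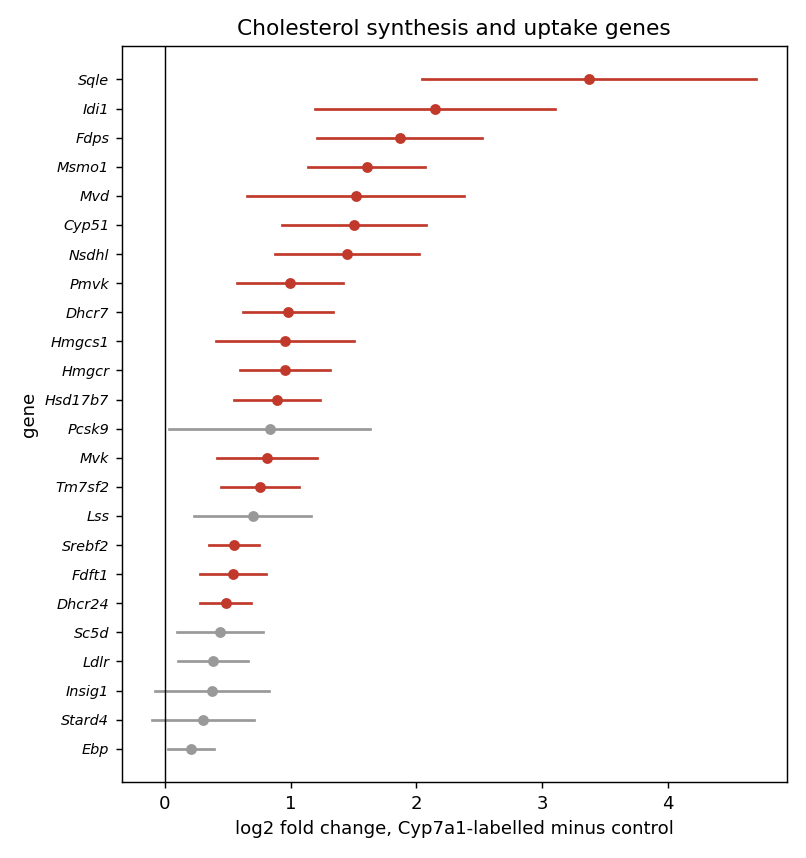
Log2 fold changes, Cyp7a1-labelled minus control (horizontal axis), of the 24 cholesterol synthesis and uptake genes (vertical axis); points are limma estimates, bars their 95% intervals, and red marks adjusted p under 0.05. All 24 estimates lie above 0, and 17 pass the threshold.

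The list of genes induced by the oxysterol receptor LXR was lower by the list test. Of 10 members, 3 were lower and 0 higher, with 4 lower adjusted over the list alone, 2 fold changes were above 0, and the median was -0.25. The sterol exporter subunits Abcg5 (chromosome 17, 84658234 to 84683011) and Abcg8 (84676302 to 84700333) had log2 fold changes of -1.26 ± 0.18 and -1.14 ± 0.20. These genes overlap on opposite strands, so shared reads cannot be excluded. Srebf1, a regulator of fatty acid synthesis, went from 11061 ± 2614 to 5513 ± 452 normalized counts (log2 fold change -0.98, adjusted p = 3.23e-05). The camera adjusted p was 0.00113, and the call held with an estimated correlation, adjusted p = 0.0357.

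In bile acid synthesis, 2 of 16 members were higher and 0 lower, with 3 higher and 2 lower adjusted over the list alone. Cyp8b1 (chromosome 9, 121914356 to 121916305), the sterol 12-alpha-hydroxylase, rose from 10503 ± 1670 to 24774 ± 4291 normalized counts (log2 fold change 1.23 ± 0.11 SE, adjusted p = 3.79e-06). Cyp39a1, an oxysterol hydroxylase, rose by 0.69 ± 0.15. The list was not called (camera adjusted p = 0.780), and its median of -0.02 and mean of 0.07 differ in sign. In bile acid and sterol transport, 2 of 12 tested members were higher and 3 lower, and 2 and 4 adjusted over the list alone (camera adjusted p = 0.514). The exporter Abcc4 rose by 0.62 ± 0.11 and the uptake carrier Slco1a4 by 0.69 ± 0.18. Abcg5, Abcg8 and Abcc3 were lower, and Abcc3, with a log2 fold change of -0.24 ± 0.07, was chosen after its values were seen. Among 11 tested genes induced by the bile acid receptor FXR, 1 was higher and 2 lower, and 1 and 3 adjusted over the list alone (camera adjusted p = 0.201). Nr0b2 and the sterol regulator Insig2 fell, Insig2 with a log2 fold change of -0.57 ± 0.14, while the phospholipid transfer protein Pltp rose by 1.09 ± 0.20.

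Fatty acid synthesis genes moved in both directions, with 2 higher and 2 lower of 21, the same counts adjusted over the list alone, and a camera adjusted p of 0.780. Srebf1 and Mlxipl (ChREBP) fell, Mlxipl with a log2 fold change of -0.68 ± 0.15, and Acss2 and the desaturase Fads1 rose by 0.94 ± 0.21 and 0.46 ± 0.10. Among genes of lipid droplets and fatty acid uptake, 2 of 21 were higher and 3 lower, and 3 and 3 adjusted over the list alone (camera adjusted p = 0.8003). Their median was 0.06 and their mean -0.02. The fatty acid binding protein Fabp2 went from 3797 ± 521 to 1828 ± 100 normalized counts (log2 fold change -1.04, adjusted p = 1.42e-07), and Fabp1 changed by -0.40 ± 0.09. Plin5 rose by 0.65 ± 0.18, and the lipase Pnpla2, chosen after its values were seen, by 0.37 ± 0.11. Fabp1 lost its call with quantile normalization (adjusted p = 0.0738).

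Of 26 tested genes of fatty acid oxidation, 2 were higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.189). Cyp4a14 rose by 1.36 ± 0.32 and Hadhb by 0.30 ± 0.07, though Hadhb lost its call with equal totals (adjusted p = 0.0837), and Vnn1 had a log2 fold change of -0.54 ± 0.15. The list passed the threshold without Control 12 (adjusted p = 0.0189) and without Cyp7a1 24 (0.0225). With an estimated correlation over all libraries its adjusted p was 0.945. In lipoprotein assembly and turnover, 1 of 20 was higher and 2 lower, and 2 and 3 adjusted over the list alone (camera adjusted p = 0.780). Besides Pltp, Scarb1, the HDL receptor, had a log2 fold change of -0.46 ± 0.09 and Angptl8 of -0.74 ± 0.21. In glucose metabolism 3 of 16 were higher and 0 lower, and 4 and 0 adjusted over the list alone. Igfbp1 rose by 1.07 ± 0.23, Ppargc1a by 0.69 ± 0.11 and Pfkfb1 by 0.39 ± 0.09. The camera adjusted p was 0.0509, and with an estimated correlation it was 0.469. It fell under the threshold without Control 20 (0.00963), Control 25 (0.0346), Control 35 (0.0455), Cyp7a1 19 (0.0281), Cyp7a1 24 (0.0221) or Cyp7a1 36 (0.0400).

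Genes induced by the xenobiotic receptors CAR and PXR were lower as a list with a preset correlation (camera adjusted p = 0.00369), and the call was lost with an estimated correlation (adjusted p = 0.294). Of 15 tested members 4 were lower and 0 higher, 5 lower adjusted over the list alone, and the median was -0.27. Cyp3a25 went from 8756 ± 732 to 6405 ± 472 normalized counts (log2 fold change -0.45, adjusted p = 0.000277). Cyp3a11 changed by -0.47 ± 0.13, Ces2a by -0.64 ± 0.16 and Ugt1a1 by -0.26 ± 0.06. Cyp3a genes have close paralogs, so reads may be shared among them.

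Stress and inflammation lists were not called. Of 16 genes of the unfolded protein and integrated stress response, 1 was higher and 2 lower, and 2 and 5 adjusted over the list alone (camera adjusted p = 0.497). Asns was the higher one, and Sesn2 and Xbp1 had log2 fold changes of -0.43 ± 0.09 and -0.34 ± 0.10. The median of this list was -0.11 and its mean 0.01. Of 11 NRF2 and oxidative stress genes, Gclc alone passed, with a log2 fold change of -0.41 ± 0.08, also adjusted over the list alone (camera adjusted p = 0.780). In the acute phase list Apcs rose by 0.70 ± 0.16 and Orm3 changed by -0.92 ± 0.20, 1 higher and 1 lower of 16, and 1 and 2 adjusted over the list alone (camera adjusted p = 0.750). Usp18 rose by 0.61 ± 0.12 as the 1 gene past the threshold of 15 in the interferon list, also over the list alone (camera adjusted p = 0.780). No p53 target of 11 passed over all genes, while 1 higher and 1 lower passed over the list alone, and Trp53inp1 had a log2 fold change of 0.39 ± 0.12 and Plk2 of -0.46 ± 0.15 (camera adjusted p = 0.780). None of 13 cell cycle genes passed (Ccnd1 0.35 ± 0.18, Birc5 -0.28 ± 0.16, camera adjusted p = 0.780), nor did any of 14 clock genes (Ciart 0.73 ± 0.30, Bhlhe41 -0.50 ± 0.25, camera adjusted p = 0.897), with 0 in either list adjusted over the list alone.

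Markers of other cell types did not differ as lists. No member passed among 11 Kupffer cell markers (Folr2 -0.24 ± 0.12, Vsig4 0.20 ± 0.12, camera adjusted p = 0.780), 11 recruited macrophage markers (Lyz2 -0.26 ± 0.18, Cd9 0.34 ± 0.23, 0.780) or 15 stellate cell and fibrosis markers (Dcn 0.11 ± 0.08, Lum 0.28 ± 0.22, 0.780). The same held for 11 sinusoidal endothelial markers (Lyve1 0.46 ± 0.20, Kdr -0.18 ± 0.09, 0.541), 3 lymphocyte markers (Cd79b 0.53 ± 0.37, Ighm 0.39 ± 0.32, 0.780) and 5 blood and carry-over genes (Hbb-bt 0.37 ± 0.41, Hbb-bs 0.22 ± 0.43, 0.780), all as log2 fold change ± SE. None of these 6 lists had a member past the threshold adjusted over the list alone. The 1 neutrophil marker tested, Csf3r, had a log2 fold change of 0.16 ± 0.23. Of 7 cholangiocyte markers only Krt23 passed, lower, also over the list alone (camera adjusted p = 0.780), and the list's median of 0.08 and mean of -0.22 differ in sign. Among 12 hepatocyte markers Tat, tyrosine aminotransferase, rose by 0.84 ± 0.24 as the 1 member past the threshold, also over the list alone (0.750). In the periportal list of 11, Aldh1b1 rose by 0.65 ± 0.16, and 2 members were higher over the list alone (0.119, 0.0248 without Cyp7a1 24, and 0.892 with an estimated correlation over all libraries). Of 11 pericentral markers none passed over all genes, and 2 higher and 1 lower passed over the list alone (Axin2 -0.31 ± 0.09, Slc1a2 0.26 ± 0.08, 0.920). The Y-linked genes Uty and Ddx3y had log2 fold changes of 0.28 ± 0.10 and 0.17 ± 0.09, not past the threshold, and 0 of 4 tested members of the sex-linked list passed.

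**Figure D3:**
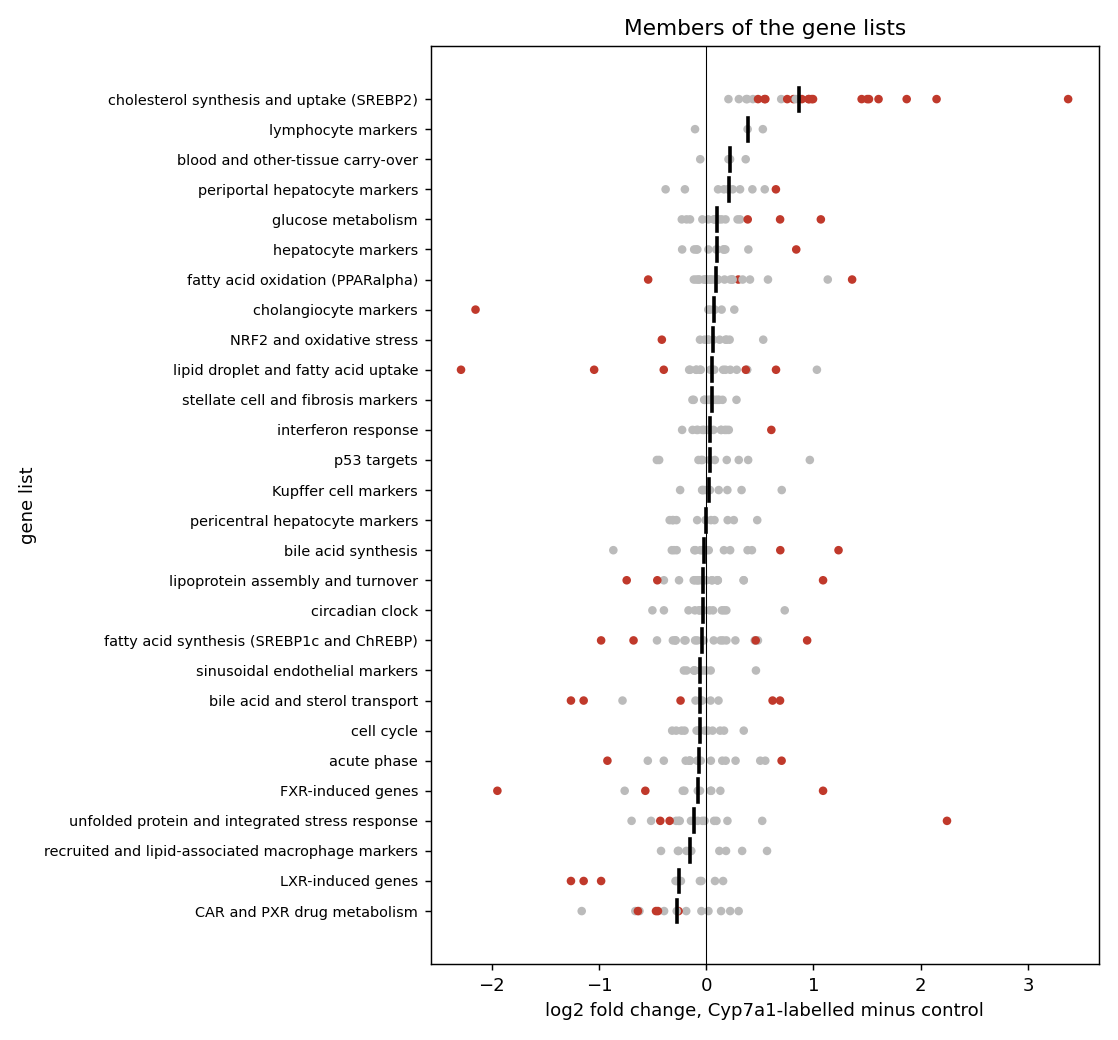
Log2 fold changes, Cyp7a1-labelled minus control (horizontal axis), of the tested members of 28 gene lists (vertical axis, ordered by median); each point is 1 gene, red marks adjusted p under 0.05 over all genes, and black bars are list medians. Cholesterol synthesis and uptake has a median of 0.86, and CAR and PXR drug metabolism has the lowest, -0.27.

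Of 61 named genes past the threshold, 45 kept their call under each alternative run on single genes and with any 1 library left out. The 1.5-fold minimum was applied to the gene counts only. The call ended when 1 library was left out for 14 genes. It ended without any of 14 libraries for Lrtm1, 12 for Plin5, 11 each for Mvd, Mup2, Xbp1 and Tat, 10 each for Vnn1 and Angptl8, 8 for Cyp3a11, 5 for Slco1a4, 3 each for Derl3 and Ces2a, 2 for Insig2 and 1 for Aldh1b1. The highest of these adjusted p values were 0.0976 for Lrtm1 without Control 16, 0.0906 for Tat, 0.0882 for Plin5, 0.0864 for Angptl8 and 0.0794 for Xbp1 without Cyp7a1 19, and 0.0752 for Mvd without Cyp7a1 28. They were 0.0754 for Mup2 and 0.0717 for Vnn1 without Control 12, and 0.0513 for Aldh1b1 without Control 38. They were 0.0708 for Cyp3a11, 0.0617 for Slco1a4, 0.0568 for Ces2a and 0.0512 for Insig2 without Cyp7a1 28, and 0.0559 for Derl3 without Cyp7a1 19. All of these kept their direction. Of the 61 genes, 56 changed in the same direction in 8 of 8 Cyp7a1-labelled livers relative to the control mean, and 5 in 7 of 8 (Mvd, Nsdhl, Slco1a4, Acss2 and Angptl8). Another setting ended the call of 12 genes. Quantile normalization ended those of Lrtm1 (adjusted p = 0.0558), Fabp1 (0.0738) and Cyp3a11 (0.103), and equal totals those of Hadhb (0.0837), Vnn1 (0.0675) and Plin5 (0.0537). Array weights ended those of Mup2 (0.0530) and Angptl8 (0.0905). Leaving out Control 20 together with Cyp7a1 24, chosen after seeing the data, ended those of Mvd (0.0646), Lrtm1 (0.0727), Derl3 (0.0560), Mup2 (0.0939), Hadhb (0.0574), Angptl8 (0.101), Ces2a (0.0511) and Xbp1 (0.0608). The 61 genes were named for large changes or small p in these same libraries, so kept calls and shared directions partly follow from that choice. Among all called genes, 229 of 387 higher and 241 of 385 lower kept their call without Cyp7a1 28.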

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

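Single libraries lay far from the other 7 of their group, by Dixon's 95% criterion, in 14 of the 228 groups of 8 looked at (170 of genes, 56 of list scores and 2 of depth). Chance gives such a library in about 1 group in 20, or 11.4 groups here, and 14 is near that number. The groups hold genes and scores that vary together in the same libraries, so this comparison is rough and settles nothing for a single library. Genes were judged on the log2 scale, but depth on the linear scale of recovered reads, where no library passed the criterion. Control 38 was still the least deep, with 13.8 M reads against 19.7 to 25.4 M in the other controls.

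Cyp7a1 36 stood apart in 5 of the 14. It had the lowest Sqle of its group (147 normalized counts, the others 654 to 2276), the lowest Fdps (223, the others 650 to 1261), the lowest Nsdhl (470, the others 1258 to 2685) and the lowest Ugt1a9 (337, the others 612 to 856). It had the highest Aldh1b1 (3854, the others 1505 to 2108).

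Control 20 had the highest Srebf1 of the controls (17100 normalized counts, the others 9089 to 12040), the lowest Vnn1 (2012, the others 3124 to 4474) and the lowest acute phase score (-0.507, the others -0.0544 to 0.290). Control 13 had the highest Lyz2 (2528, the others 1150 to 1660) and the highest Kupffer cell score (0.5998, the others -0.362 to 0.0109). Control 7 had the highest Ighm (655, the others 142 to 281).

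Cyp7a1 24 had the highest Csf3r of its group (224 normalized counts, the others 55.6 to 104) and the highest Birc5 (41.7, the others 28.2 to 33.2). Cyp7a1 5 had the highest Cyp2d40 (620, the others 416 to 494).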

How the results depend on the processing

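The pair of added alternatives, leaving out both Control 20 and Cyp7a1 24 and the macrophage and fibrosis covariate, was chosen after seeing the data. The cause of a change was not tested unless stated. No filter and the minimum mean of 10 remove nothing, so that comparison is void. No paired analysis was possible because the groups share no replicate numbers.

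Gene counts. Against 387 higher and 385 lower, the other scalings, pseudocount, filter, weights and count tools gave 263 to 548 higher and 372 to 573 lower. The lowest higher count came from equal totals (263 and 372) and the highest of both from DESeq2 (548 and 573). edgeR shared 368 of its 381 higher and 358 of its 379 lower genes with limma. With the covariate the counts were 655 and 654, and these included all 387 and 385. Leaving out both ends gave 383 and 331. A change of at least 1.5-fold left 111 and 83, by construction. Leaving out 1 library gave 230 to 399 higher and 245 to 414 lower, lowest without Cyp7a1 28, while 256 were lower without Control 16. The Cyp7a1 log2 fold change stayed above 0 and short of the threshold in all alternatives run, 0.33 to 0.53 with 1 library left out.

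Lists called. Against 3, an estimated correlation called 1 and leaving out both ends of the first component 6. Leaving out 1 library called 3 to 6, with 6 without Cyp7a1 24. An estimated correlation ended the calls of cholesterol synthesis and uptake (adjusted p = 0.235, and 1.55e-30 to 0.235 over all alternatives run) and of CAR and PXR drug metabolism (0.294, and 0.000102 to 0.294). Members of these lists vary together, with estimated correlations of 0.646 and 0.108 against the preset 0.01. The LXR list was estimated at 0.0056, under the preset, yet its adjusted p rose from 0.00113 to 0.0357. Correlation alone therefore need not account for the lost calls. The LXR list was called in every alternative run, adjusted p = 1.16e-05 to 0.0357. Glucose metabolism passed with quantile normalization (0.0475), equal totals (0.0181), array weights (0.00698), edgeR (0.0245), DESeq2 (0.0252), fry (0.0412), the covariate (0.0443) and both ends left out (0.00598), and ranged from 0.00963 to 0.105 with 1 library left out. With both ends left out, hepatocyte markers (0.0426) and periportal markers (0.0224) also passed. With an estimated correlation over all libraries the adjusted p was 0.469 for glucose metabolism, 0.945 for hepatocyte markers and for fatty acid oxidation, and 0.892 for periportal markers. With 1 library left out, fatty acid oxidation ranged from 0.0189 (without Control 12) to 0.519 and periportal markers from 0.0248 to 0.276. The mixed test of fry takes change in either direction. Its adjusted p was 4.39e-09 for bile acid synthesis, 4.35e-09 for lipid droplets, 1.50e-06 for FXR and 7.12e-07 for the stress response. It was 0.735 for cell cycle and 0.788 for stellate cell markers. A few changed members can pass this test, so it shows no shared shift.

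Lists that changed direction were not called either way. Their adjusted p values were 0.979 for cell cycle with a mean of at least 50, 0.907 for NRF2 with DESeq2 and 0.981 for pericentral markers with fry. With array weights they were 0.959 for fatty acid synthesis, 0.907 for the clock, 0.959 for Kupffer cell, 0.864 for stellate cell and 0.907 for pericentral markers. With both ends left out they were 0.843 for lipoproteins, 0.836 for the clock, 0.477 for Kupffer cell, 0.270 for stellate cell, 0.981 for blood and 0.835 for pericentral markers. With 1 library left out, the ranges of lists that turned at least once were 0.335 to 0.998 for bile acid synthesis, 0.489 to 0.943 for fatty acid synthesis, 0.420 to 0.997 for lipid droplets, 0.624 to 0.987 for lipoproteins, 0.522 to 0.997 for cell cycle, 0.280 to 0.973 for interferon, 0.713 to 0.987 for the clock, 0.544 to 0.993 for Kupffer cell, 0.360 to 0.963 for recruited macrophage, 0.4926 to 0.973 for stellate cell and 0.723 to 0.996 for pericentral markers.

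Named genes. With 1 library left out, 1238 of 1360 values kept direction and side of the threshold, 112 lost the call, 9 gained it and 1 turned, Csf3r (-0.043 to 0.24, lowest without Cyp7a1 24). The gains were Trp53inp1 without Control 7 (adjusted p = 0.0267), Control 25 (0.0495) or Cyp7a1 2 (0.0498), Axin2 without Control 7 (0.00592) or Cyp7a1 2 (0.0470), Slc1a2 without Control 25 or Cyp7a1 24 (0.0471 each), and Uty without Control 35 (0.0484) or Cyp7a1 5 (0.0412). Under the other alternatives 819 of 848 kept both, 16 lost the call, 11 gained it and 2 turned, Csf3r (-0.074) and Hbb-bs (-0.068) with both ends left out. Depth limits low genes most, and the least deep library, Control 38, held 13.8 M reads.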

Other observations

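The tests of Control 7, the relations with the macrophage and fibrosis score within groups, the families of genes by symbol and the test of the first principal component were chosen only after results were seen. Mup17, Mup2 and Csad are in no gene list and were named only for their large changes. The tests on them below therefore also followed from the results.

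Genes grouped by the stem of their symbol gave further sets. Of 361 families with at least 5 members, camera called 9 at the preset correlation and 0 with an estimated correlation. Most stems end at the first digit of a symbol, so a family can take in genes of other function. Genes with the stem Rpl or Rps, which ribosomal protein genes carry, lay slightly higher in the Cyp7a1-labelled livers. The median log2 fold change was 0.10 for 59 Rpl genes (camera adjusted p = 3.44e-05, and 0.995 with an estimated correlation). It was 0.11 for 46 Rps genes (0.000307 and 0.995). The 62 Atp genes had a median of 0.09 (0.00137 and 0.895) and the 20 Cox genes of 0.11 (0.0237 and 0.995). Few members passed the threshold singly, 3 Rpl, 3 Rps, 9 Atp and 2 Cox genes, all higher. Lower families were Cyp2d (7 genes, median -0.19), Cyp3a (5, -0.45), Mup (18, -0.72), Abcg (5, -0.27) and Hsd (13, -0.32). Their camera adjusted p values were 0.000368, 0.00137, 0.0060, 0.0103 and 0.0237 in that order, and 0.895 or 0.995 with an estimated correlation. Past the threshold singly, 2 Cyp2d, 3 Cyp3a, 3 Mup, 2 Abcg and 5 Hsd genes were lower, and 1 Hsd gene was higher. These 9 medians kept their sign with quantile normalization and with equal totals.

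The first principal component held 29.0% of the variance and ran from Control 20 to Cyp7a1 24. Its mean was -6.58 ± 19.9 in controls and 6.58 ± 14.7 in Cyp7a1-labelled livers (SD, n = 8 each, two-sided exact permutation p = 0.155). The macrophage and fibrosis score was -0.0044 ± 0.642 in controls and 0.0044 ± 0.414 in the other group (exact permutation p = 0.974).

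Chance alone is an unlikely source of the counts of changed genes, though 100 splits cannot show a share under 1 in 100. Among 100 splits of the 16 libraries into 8 and 8, 1 gave as many genes higher as the real split, namely the real split itself, and likewise 1 for genes lower. The real counts were 387 and 385, and the highest in either direction among the other splits was 209. That split had 4 Cyp7a1-labelled libraries on either side and called 271 genes, so a grouping unlike the labels can also give many calls. No gene was called in 93 of the other splits.

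The rise of the cholesterol synthesis and uptake score, 1.03 (95% interval 0.55 to 1.51), is hard to assign to sequencing depth or clock phase. With sequencing depth as a term it was 1.06 (0.52 to 1.61) and with a clock phase score 1.12 (0.66 to 1.58), both with an interval that excludes 0. The macrophage and fibrosis score had like means in both groups, so adding it (1.02) was bound to leave the difference in place and decides nothing. The labelled edit stays open as a cause that was not tested, and the Cyp7a1 transcript itself was not lower. The labels give no batch, so batches stay untested.

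One open reason why the Cyp7a1 transcript was not lower is an edited gene whose transcript is kept. With any 1 library left out the Cyp7a1 log2 fold change stayed at 0.33 to 0.53. This argues against 1 mislabelled library as the cause. Over genes called without it, each of the 16 libraries but 1 lay closer to the mean of its own group. The highest ratio of own to other distance among these was 0.749, for Cyp7a1 36. This argues against several mislabelled libraries. The 1 exception, Control 7, lay closer to the mean of the other group (distance 13.8 to the control mean and 13.6 to the other). Of 186 genes that separated the other 15 libraries without overlap, however, Control 7 lay nearer the mean of the Cyp7a1-labelled livers for 39.8%, against 70.9% to 92.4% for these livers when held out and 8.70% to 28.65% for the other controls. This argues against Control 7 being a liver of the Cyp7a1-labelled group, while a mixed sample stays open, and without Control 7 the Cyp7a1 log2 fold change was 0.36 (95% interval -0.06 to 0.78). Whether a transcript was kept with its feedback lifted cannot be told apart from a gradient between livers by the relation of Cyp7a1 with Cyp8b1 (r = 0.868), and an exchange of the groups as a whole was not addressed.

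Within the 8 Cyp7a1-labelled livers Cyp7a1 rose with Cyp8b1 (Pearson r = 0.868, exact permutation p = 0.00707; Spearman rho = 0.857, p = 0.0107; r = 0.814 without the 2 livers farthest from the Cyp8b1 median). Over 10 relations the adjusted p values were 0.0707 and 0.107, which miss the threshold. Both genes fell with the macrophage and fibrosis score in these livers, Cyp8b1 with r = -0.870 (exact permutation p = 0.00687, rho = -0.833, p = 0.0154, r = -0.956 without the 2 farthest) and Cyp7a1 with r = -0.863 (exact permutation p = 0.00871, rho = -0.762, p = 0.0368, r = -0.823). The hepatocyte marker score fell with it as strongly (r = -0.879, exact permutation p = 0.00461; rho = -0.738, p = 0.0458; r = -0.882), and in controls too (r = -0.961, exact permutation p = 7.44e-05; rho = -0.976, p = 0.000397; r = -0.946), so the relation is not particular to Cyp7a1 and Cyp8b1. With the score removed from both genes r was 0.471 (permutation p = 0.227). Adjusted over these 8 relations, counting both groups, p was 0.0174 for Cyp8b1, for Cyp7a1 and for the hepatocyte score, 0.302 with the score removed, and 0.000595 for the hepatocyte score in controls. In controls the score had r = 0.105 with Cyp8b1, of the opposite sign (exact permutation p = 0.812, adjusted 0.812; rho = 0.214, p = 0.619; r = -0.348 without the 2 farthest), and r = -0.553 with Cyp7a1 (exact permutation p = 0.156, adjusted 0.249; rho = -0.690, p = 0.0694; r = -0.841). With the score removed r was 0.451 in controls (permutation p = 0.264, adjusted 0.302). Among controls alone Cyp7a1 and Cyp8b1 had r = 0.315 (exact permutation p = 0.453), and the difference between the groups was not tested.

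The falls of Mup17 and Mup2, on average -1.76 on the log2 scale, may partly reflect reads shared between near-identical Mup genes. The summed value of all 18 Mup genes differed by -0.83 (95% interval -1.40 to -0.26), which is less than 0.5 of that fall, as this explanation needs, but by a small margin that the interval spans. Mup17 and Mup2 were named for being among the largest falls, so a smaller change of the sum is likely in any case. Of the 18 Mup genes 16 had a fold change below 0, with 3 lower and 0 higher past the threshold, and the highest was 0.26. The sum itself was lower, which an exchange of reads among Mup genes would not give, so the explanation stays open for part of the fall only. Adding the macrophage and fibrosis score (-1.75) decides nothing here either, since its means were alike in both groups. A biological difference between the groups stays open.

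A single sterol signal that varies between livers could link a high cholesterol synthesis score with a low LXR-induced score within a group. The data do not decide. Pearson r was -0.226 in the Cyp7a1-labelled livers (exact permutation p = 0.588, adjusted 0.653; Spearman rho -0.214, p = 0.619; r = 0.00031 without the 2 farthest livers) and -0.163 in controls (p = 0.714, adjusted 0.714; rho -0.381, p = 0.360; r = -0.0077). In the Cyp7a1-labelled livers the cholesterol synthesis score rose with Csad (r = 0.794, exact permutation p = 0.0149, adjusted 0.0747; rho = 0.690, p = 0.0694; r = 0.611 without the 2 farthest), short of the threshold after adjustment. The other 6 of the 10 relations had adjusted p values of 0.653.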
